A study of Homo sapiens with 9 samples.

How the data were processed

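Gene expression was measured in MeWo cells, an established human melanoma line, on 9 Clariom S arrays, 3 for each of 3 groups: scrambled shRNA, shRNA against HSF1 and shRNA against CBFA2T2. Per the labels' protocols, total RNA was isolated with an RNeasy Mini Kit and biotinylated cDNA was prepared from 100 ng of it with a WT PLUS kit. Groups were taken from the sample titles. The labels give neither the number nor the sequences of the shRNAs per target, so off-target effects cannot be told apart from loss of the targeted gene. The descriptive text of the CBFA2T2 samples speaks of embryos, not of this cell line, and was set aside, and the genotype tags write knockout where the titles write knockdown. Nothing in the labels says whether the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

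The deposited values were a table of log2 probe set summaries, made by the authors with Partek 6.6 per the submitters' processing notes. The background correction, the normalization, the summarization, the centring and the genome build are not given in the sources used here. The log base is not stated either. Base 2 was inferred and stays an assumption. The deposited maxima reach 19.8, above 16, the log2 limit of a 16-bit scanner, so the summaries are not plain log2 intensities, and a larger base would need still larger intensities. Column medians over the tested probe sets ran from 6.17 to 6.26. No scanner files and no detection calls were used here, so the number of arrays and the level of control probe sets are the only guides to precision. Negative control probe sets had a median of 4.70 over all arrays and a 95th percentile of 8.17. Of 60 named extremes, 36 had a dimmer group under that percentile, so the size of their fold rests on signal near background. The percentile lay above the median of all tested values, 6.21, and below the upper quartile of each array, 8.74 to 8.97. Most tested values thus lay under it as well, and 36 of 60 does not set the named genes apart.

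The table had 24351 lines. Control probe sets, among them 2197 positive control exons and 612 negative control introns, were left out, and 21448 probe sets were tested. The platform annotation named 1 gene for 17709 of these, several for 0 and none for 3739, and 0 symbols changed when they were looked up by Entrez identifier in the RefSeq gene table of assembly GRCh38.p14, which was used for names only. No coordinates are given because the build behind the probe sets is not named. Where a gene had several probe sets, the one with the highest mean was used in gene lists.

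A linear model with 1 coefficient per group was fitted to the values as deposited, over all 9 arrays, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and 3 contrasts were drawn from it. It had 6 residual degrees of freedom. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Errors beside log2 differences are the standard errors (SE) of this model, and errors beside group levels are standard deviations (SD) over 3 arrays. The 32 gene lists held 635 distinct genes, of which 580 were matched and 55 were not analysed here. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Adjusted p-values of lists were computed over the 32 lists of a comparison.

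The comparisons, the lists, the alternatives and the rule for the genes that are named were fixed before the data were examined. The rule took the targeted genes, the 12 highest and 12 lowest fold changes against the control and the 6 highest and 6 lowest between the knockdowns, among called probe sets with 1 symbol, no overlap between the arrays of the groups and a brighter group above the median of all tested values of 6.21. It also took the 8 genes per direction with the largest smaller change in both knockdowns, up to 5 genes called in opposite directions, and the 4 members of each described list with the largest change in size, called or not.

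Because both knockdowns share their control arrays, 100 sets of 9 unchanged arrays were simulated, with 3 as controls shared by the other groups. The real control arrays did not enter. Each value was drawn independently around its probe set's mean over all arrays, with the model's spread. The procedure was tested on simulated data with the spread of these arrays before use. For the HSF1 comparison, 50 of 21448 probe sets were changed at each size. The procedure recovered 2% of log2 changes of 0.5, 52% of changes of 1, 98% of changes of 1.5 and 100% of changes of 2, with 6 false calls. So few simulated changes make the adjusted p stricter than in the data, where far more probe sets were called. The shares are thus not the sensitivity of the real comparisons.

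The alternatives were quantile normalization, centring of array medians, removal of the dimmest 30% of probe sets, a trended and robust prior, no moderation, a fit of only the 6 arrays compared, the replicate number as a block, array weights, and each array left out. Scaling each array to its 4 hybridisation controls was added after seeing the data. It moved the median log2 difference of all probe sets to -0.77 in the HSF1 knockdown and -0.88 in the CBFA2T2 knockdown, so changes are reported relative to the level of the whole array. Figures were drawn with matplotlib 3.10.9.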

Results

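Messenger RNA levels were compared on 9 arrays of MeWo melanoma cells in which HSF1, the main transcription factor of the heat shock response, or CBFA2T2, a corepressor of the ETO family, was knocked down with shRNA. The series asked which genes are regulated by either knockdown, with a scrambled shRNA as control and 3 arrays in each group. Correlations across probe sets, which are not independent replicates, ran from 0.986 to 0.991 within groups and from 0.977 to 0.984 between groups. The first principal component, with 33.5% of the variance, set the control arrays apart from both knockdowns, while the next, with 17.0%, parted the knockdowns from each other. The 4 hybridisation controls, bacterial and phage transcripts added in fixed amounts before hybridisation, had a mean log2 level of 10.6 ± 0.12 (SD, n = 3) in control arrays, 11.3 ± 0.06 in HSF1 knockdown arrays and 11.5 ± 0.21 in CBFA2T2 knockdown arrays.

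Both targeted genes were lower in the cells made to target them. HSF1 had a log2 level of 9.25 ± 0.13 (SD, n = 3) in control cells, 6.12 ± 0.09 in HSF1 knockdown cells and 9.13 ± 0.06 in CBFA2T2 knockdown cells. That was an 8.78-fold decrease in the HSF1 knockdown (log2 difference -3.13, SE 0.16; limma adjusted p = 4.6e-06), while the difference of -0.11 in the CBFA2T2 knockdown was not called (adjusted p = 0.73) and was 0.05 after quantile normalization. CBFA2T2 was at 7.23 ± 0.21 in control cells and 5.91 ± 0.43 in its own knockdown, a 2.49-fold decrease (log2 difference -1.32, SE 0.22; limma adjusted p = 0.0028). Its arrays in that knockdown read 5.62, 6.40 and 5.71. In HSF1 knockdown cells CBFA2T2 was at 6.76 ± 0.06, and the difference of -0.46 was not called (limma adjusted p = 0.21), although those arrays did not overlap the control arrays. Against 8.17, the 95th percentile of negative control probe sets, HSF1 lay below in its own knockdown and CBFA2T2 in all 3 groups. The sizes of these folds thus rest on signal near background, though most tested values also lay below that percentile.

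**Figure D1:**
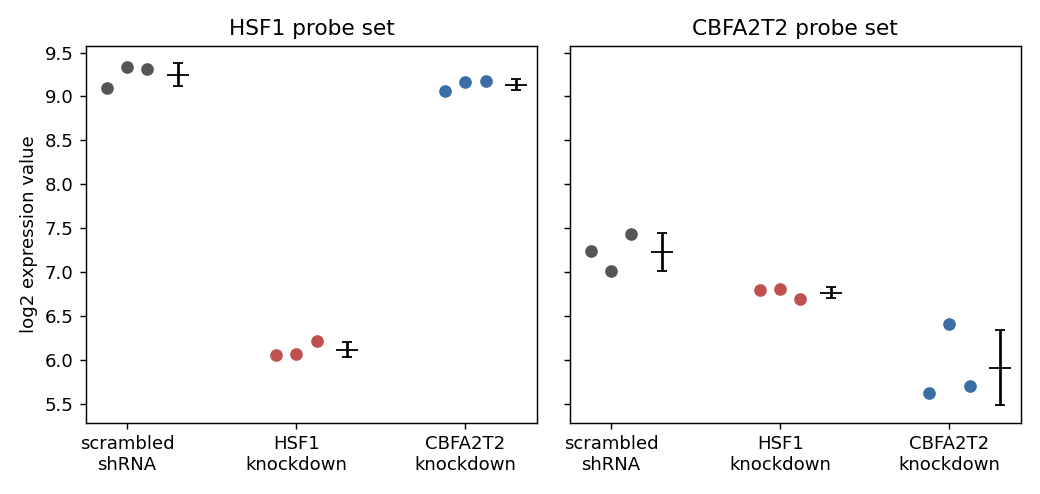
Log2 expression values of the HSF1 probe set (left) and the CBFA2T2 probe set (right) on each of 9 arrays, with the mean and SD of 3 arrays as a bar beside each group. HSF1 sits near 6.12 in its knockdown against 9.25 in control cells, and CBFA2T2 near 5.91 in its knockdown against 7.23.

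In HSF1 knockdown cells SERPINE2, a secreted protease inhibitor, was 9.24-fold higher than in control cells (log2 difference 3.21, SE 0.28, limma adjusted p = 0.00016). That was the highest fold among genes that met the rule for named genes, and the other folds here are ranked within the same rule. Also higher were NKX1-1, a homeobox gene, by 2.35 on the log2 scale, the carboxypeptidase CPA4 by 1.99, the cytokine IL6 by 1.92 and the anthrax toxin receptor ANTXR2 by 1.88. Among the other genes with the highest folds were ADRM1, a ubiquitin receptor of the proteasome, at 1.84, the chaperonin subunit CCT7 at 1.72, the mitochondrial assembly factor BCS1L at 1.81, the ribosomal protein paralog RPL26L1 at 1.80, the interleukin receptor IL7R at 1.73, the dipeptidase PEPD at 1.72 and the annexin ANXA3 at 1.70. After HSF1 itself, the lowest were TMT1A at -2.96 (SE 0.22), the complement protease homolog C1RL at -2.83, the xylosyltransferase GXYLT2 at -2.62, VIT at -2.53 and CCNG2, a cyclin, at -2.44. C1QTNF6 at -2.38, SPINK13 at -2.37, the sphingosine phosphatase SGPP1 at -2.26, the calcium channel subunit CACNB2 at -2.25, DSEL at -2.23 and NRSN2 at -2.23 completed the 12 lowest.

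In all, 769 probe sets were higher and 1646 lower in HSF1 knockdown cells, 11.3% of 21448, and 270 and 636 of these changed at least 2-fold. The arrays of the groups did not overlap at 31.4% of probe sets, where chance gives 10%. After quantile normalization the split was 1063 higher and 1078 lower. With 1 array left out, the higher and lower counts were 407 and 1052 without control replicate 1, 410 and 958 without control replicate 2, 543 and 1077 without control replicate 3, 449 and 988 without HSF1 knockdown replicate 2 and 484 and 1046 without its replicate 3, and at most 784 and 1658, without CBFA2T2 knockdown replicate 1.

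Genes of cholesterol and lipid synthesis fell together in HSF1 knockdown cells: 16 of 20 measured members were lower and 0 higher (18 lower adjusted over the list alone; camera adjusted p = 1.3e-13, and adjusted p = 0.027 with an estimated correlation). INSIG1, which holds the sterol sensor in the endoplasmic reticulum, fell by 2.04 on the log2 scale (SE 0.17), the sterol oxidase MSMO1 by 1.90, the transcription factor SREBF2 by 1.60 and the synthase HMGCS1 was 2.83-fold lower. Proteasome subunits rose, 12 of 27 (20 adjusted over the list alone; camera adjusted p = 3.6e-12, and adjusted p = 0.056 with an estimated correlation), with PSMC3 at 1.67, PSMB7 at 1.51 and PSMD4 at 1.31. The TRiC chaperonin, which folds actin and tubulin, had 3 of 7 subunits higher (6 adjusted over the list alone; camera adjusted p = 2.8e-05, and adjusted p = 0.056 with an estimated correlation), led by CCT7 at 1.72 and CCT2, 2.01-fold higher. In the list of endoplasmic reticulum chaperones and unfolded protein response genes, 6 of 19 were lower (9 adjusted over the list alone). Camera gave adjusted p = 1.1e-05, and adjusted p = 0.056 with an estimated correlation. Among the lower members were EDEM1, 2.82-fold lower, SEL1L at -0.89 and DNAJC3 at -0.74.

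The chaperones of the heat shock response, the best known targets of HSF1, moved in both directions. Of 26 measured members 5 were lower and 2 higher in HSF1 knockdown cells (5 and 2 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.67). Its median difference was -0.11, and its direction in the test turned upward after quantile normalization, without the dimmest 30% of probe sets and without control replicate 3. The members with the largest change were HSPB1 at -0.83 (SE 0.23; limma adjusted p = 0.037), HSPD1 at -0.77, HSPH1 at -0.73 and STIP1 at 0.72. Calls of HSPB1, HSPD1 and HSPH1 ended after quantile normalization, and those of HSPB1 and HSPH1 also after median centring and without moderation. HSPB1 lost its call with 5 of the 9 arrays left out in turn (highest adjusted p = 0.13, without control replicate 3), HSPH1 also with 5 (0.11, without control replicate 2) and STIP1 with 2 (0.067, without control replicate 1). HSPA8, HSPA1B, AHSA1 and CDC37 were among the members not analysed here. Of the list set up for HSF paralogs, 2 genes were measured, HSF5 at 0.17 and HSF2BP, which encodes a binding partner of HSF2 and is no paralog, at 0.56. Of these, 0 were called (1 higher adjusted over the list alone).

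Interferon-stimulated genes were higher, 8 of 26 (10 adjusted over the list alone; camera adjusted p = 1.1e-05, and adjusted p = 0.056 with an estimated correlation), with HERC5 at 1.68, ISG15 at 1.56, IFIT1 at 1.07 and RIGI, a sensor of viral RNA, at 1.04. The call of IFIT1 ended with 4 of 9 arrays left out in turn (highest adjusted p = 0.073, without HSF1 knockdown replicate 2). ERK pathway targets had 5 of 20 higher (6 adjusted over the list alone; camera adjusted p = 0.00036, and adjusted p = 0.15 with an estimated correlation), including IER3 at 1.48 and the phosphatases DUSP6 at 1.24 and DUSP5 at 1.09. Another 5 lists passed camera at the preset correlation. Ribosome biogenesis had 2 of 20 higher (2 adjusted over the list alone; adjusted p = 0.056 with an estimated correlation), with PES1 at 1.10 and RRP9 at 0.82. PES1 lost its call with 4 arrays left out in turn (highest adjusted p = 0.10, without control replicate 2) and RRP9 with 3 (0.072, without control replicate 1). Histones had 4 of 19 lower (7 adjusted over the list alone; adjusted p = 0.44 with an estimated correlation), with H1-5 at -1.12. NRF2 targets had 3 of 17 higher (3 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), TXN at 1.26, FTL at 1.12 and PRDX1 at 0.77. This list's call ended without control replicate 1 (adjusted p = 0.054). Oxidative phosphorylation had 5 of 21 higher (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.45 with an estimated correlation), with COX5A at 1.02. Its call ended without control replicates 1 or 2 or HSF1 knockdown replicate 1, at adjusted p of 0.066, 0.079 and 0.073, and fry did not call the list (0.13). Targets of p53 had 4 of 19 lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation), with CDKN1A at -1.38, not called without moderation, and TNFRSF10B at -1.19. The p53 list's call ended after quantile normalization (adjusted p = 0.098) and without the dimmest 30% (0.068). The lists of the dedifferentiated melanoma state (adjusted p = 0.078) and of NF-kB (0.19) were not called. The first was called after quantile normalization (0.039), without the dimmest 30% (0.013) and without control replicate 3 (0.042), and the NF-kB list without the dimmest 30% (0.047). Fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, called both (0.0074 and 0.032), and also S phase genes (0.0014) and G2 and mitosis genes (0.014), which camera did not call. With an estimated correlation the cholesterol list alone was called, where the preset correlation called 11 of 32.

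Among genes that met the rule for named genes, IL7R had the highest fold in CBFA2T2 knockdown cells. It rose 5.08 on the log2 scale (SE 0.22, limma adjusted p = 3.7e-07). IL6 rose 4.45, NT5E, the ecto-enzyme CD73, 4.30, CPA4 4.13 and the membrane protein CDCP1 4.03. DUSP5, a phosphatase of ERK, was higher by 3.71, ANTXR2 by 3.69, SERPINE2 by 3.62, the integrin ITGA2 by 3.03, MCTP2 by 2.95, MYH15 by 2.81 and the aminopeptidase ANPEP by 2.75. The lowest folds within that rule belonged to VIT at -4.30 (SE 0.26), TMT1A at -3.67, GXYLT2 at -3.64, the small GTPase RAB26 at -3.08 and the kinase MYLK3 at -3.00. HSD17B13 at -2.88, CACNB2 at -2.75, MFSD6 at -2.71, LMO1 at -2.70, ZNF652 at -2.60, SLC12A3 at -2.46 and C1RL at -2.46 followed. SLC12A3 was at 4.05 in the knockdown, below the median of negative control probe sets, so its fold has no firm size.

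In CBFA2T2 knockdown cells 674 probe sets were higher and 1458 lower, 9.94% of those tested, with 260 and 695 changed at least 2-fold and 29.0% not overlapping. Quantile normalization gave 859 higher and 1030 lower. Leaving out 1 array gave from 360 higher and 918 lower, both without control replicate 2, to 646 and 1441 without HSF1 knockdown replicate 1; control replicate 1 left 412 and 987, and control replicate 3 left 437 and 965.

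Cholesterol and lipid synthesis was again the list with the smallest p, with 18 of 20 members lower (18 adjusted over the list alone; camera adjusted p = 5.0e-20, and adjusted p = 0.0096 with an estimated correlation). INSIG1 was at -2.20, SREBF1, a transcription factor of lipid synthesis, at -1.69, HMGCS1 at -1.48, and STARD4 was 2.83-fold lower. Interferon-stimulated genes were higher, 13 of 26 (13 adjusted over the list alone; camera adjusted p = 5.7e-09, and adjusted p = 0.029 with an estimated correlation), with IFIT1 at 2.17, RIGI at 2.02 and ISG15 at 1.98. Inflammatory genes of the NF-kB list were higher, 6 of 21 (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.6e-06, and adjusted p = 0.021 with an estimated correlation), with NFKB2 at 2.22, TNFAIP3 at 2.19 and ICAM1 at 1.61 after IL6. ERK targets were higher, 7 of 20 (11 adjusted over the list alone; camera adjusted p = 5.7e-09, and adjusted p = 0.038 with an estimated correlation), with IER3 at 2.63, PHLDA1 at 2.42 and DUSP4 at 1.81. Genes of the dedifferentiated melanoma state had 8 of 20 higher and 2 lower (10 and 3 adjusted over the list alone; camera adjusted p = 7.0e-05, and adjusted p = 0.029 with an estimated correlation), with NT5E, the AP-1 subunit FOSL1 at 2.28 and CCN2 at 1.92.

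Another 7 lists passed at the preset correlation and not with an estimated one. G2 and mitosis genes had 6 of 27 lower (9 adjusted over the list alone; adjusted p = 0.092 with an estimated correlation), with the proliferation marker MKI67 at -1.24, CENPF at -1.06 and KIF20A at -0.98. The call of CENPF ended without control replicate 2 or CBFA2T2 knockdown replicate 3 (adjusted p = 0.069 and 0.058) and without moderation. S phase genes had 4 of 26 lower and 1 higher (4 and 1 adjusted over the list alone; adjusted p = 0.082 with an estimated correlation), with E2F1 at -1.48 and MCM6 at -0.89. Quantile normalization ended this call (adjusted p = 0.14). Heat shock chaperones had 6 of 26 higher and 0 lower (7 adjusted over the list alone; camera adjusted p = 0.0024, and adjusted p = 0.11 with an estimated correlation), with DNAJB6 at 0.93, DNAJA1 at 0.84, SERPINH1 at 0.81 and HSP90AA1 at 0.80. DNAJA1 lost its call with 2 arrays left out in turn (highest adjusted p = 0.057) and SERPINH1 with 5 (0.12), both highest without control replicate 2, and SERPINH1 also without moderation. Proteasome subunits had 8 of 27 higher (9 adjusted over the list alone; adjusted p = 0.095 with an estimated correlation), with PSMB7 at 0.85 and PSMC3 at 0.82. The TRiC list had 2 of 7 higher (3 adjusted over the list alone), CCT7 at 0.86 and CCT2 at 0.76. Ribosome biogenesis had 2 of 20 higher (2 adjusted over the list alone), PES1 at 0.97 and NPM1 at 0.69, and this call ended without control replicate 1 (adjusted p = 0.070). PES1 and NPM1 each lost their own calls with 7 of 9 arrays left out in turn (highest adjusted p = 0.18 and 0.16, both without control replicate 2). Both lists had adjusted p = 0.095 with an estimated correlation. Histones had 6 of 19 lower (8 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation), with H1-5 at -1.49 and H1-2 at -1.34. Targets of p53 were not called (adjusted p = 0.068), but were without control replicate 1 (0.037) or CBFA2T2 knockdown replicate 3 (0.022), and by fry (0.0021). The list of endoplasmic reticulum chaperones and unfolded protein response genes was called by fry alone (0.0036).

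**Figure D2:**
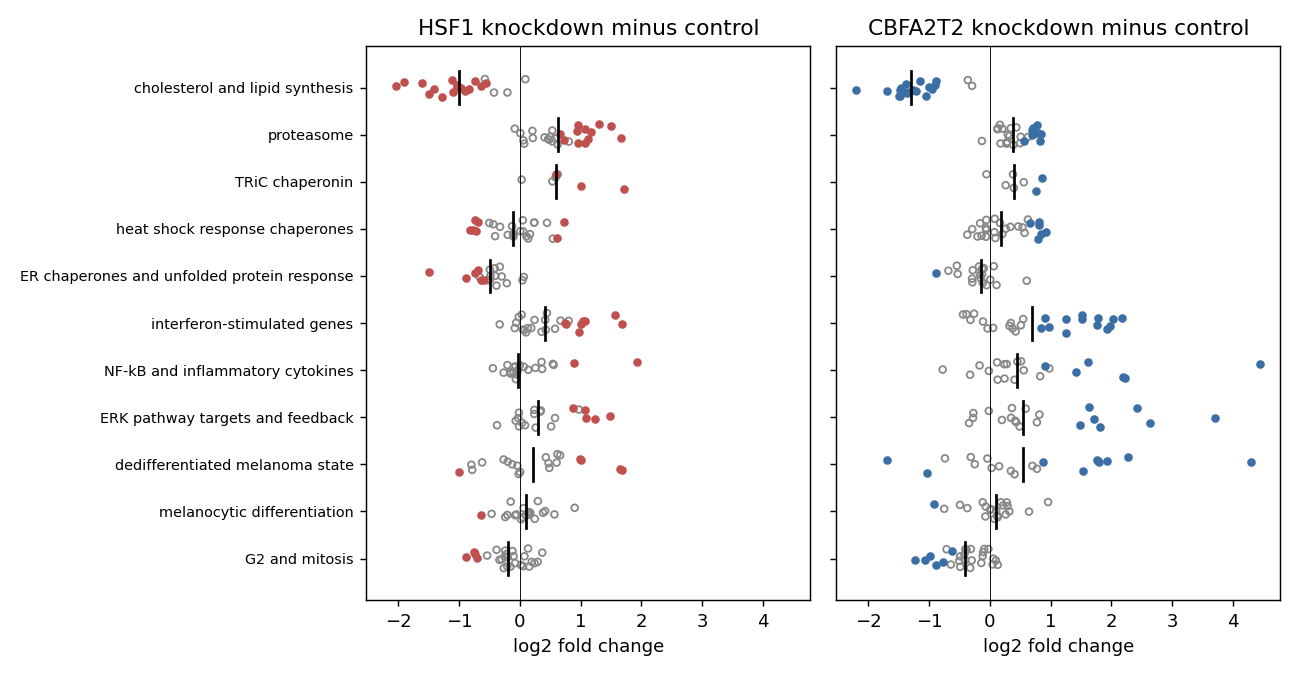
Log2 fold changes of the measured members of 11 gene lists in HSF1 knockdown (left) and CBFA2T2 knockdown (right) against control. Filled points were called, open points were not, and black bars are list medians, which for heat shock chaperones lie at -0.11 and 0.19, where the test of the first turns upward after quantile normalization, and for cholesterol synthesis at -1.30 in the CBFA2T2 knockdown.

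Melanocytic differentiation genes were not called as a list in either knockdown (camera adjusted p = 0.36 and 0.55). GPNMB, a melanosomal glycoprotein, was the 1 called member of 21 in each (0 and 1 adjusted over the list alone), at -0.64 and -0.91. Its call in the HSF1 knockdown ended after quantile normalization, after median centring and with 6 of 9 arrays left out in turn (highest adjusted p = 0.12, without control replicate 1). PMEL was at 0.90 and 0.96, not called. In the list of the ETO family and its partners, SIN3A was at -1.41 and -1.06 and LDB1, an adaptor of LIM domain factors, at -1.21 and -1.25, and the list was not called (camera adjusted p = 0.89 and 0.48). The call of SIN3A in the CBFA2T2 knockdown ended without control replicates 1 or 2 (highest adjusted p = 0.061) and without moderation. None of the marker lists of keratinocytes, fibroblasts, leukocytes or endothelial cells was called against control by camera; fry called the keratinocyte list in both (adjusted p = 0.048 and 0.034). Among their members KRT18 was at 1.24 and 0.99, and in the CBFA2T2 knockdown COL1A2 was at -1.06 and CD68 at 1.11. The lists of antigen presentation, glycolysis, Wnt targets, Notch targets, immediate early genes, matrix genes, autophagy, apoptosis regulators and ATF4 targets were not called against control by camera either. Fry called antigen presentation (adjusted p = 0.032), glycolysis (0.033) and ATF4 targets (0.014) in the HSF1 knockdown, and Notch targets (0.022) and the ETO list (0.048) in the CBFA2T2 knockdown. In the CBFA2T2 knockdown immediate early genes were called without control replicate 3 (adjusted p = 0.032) or CBFA2T2 knockdown replicate 1 (0.034), as was the keratinocyte list without the latter (0.034). ATF4 targets (0.030), autophagy (0.030) and NRF2 targets (0.040) were called there after quantile normalization, and ATF4 targets and immediate early genes without the dimmest 30% (both 0.0496). Median, mean and test differed in sign for the NF-kB, autophagy and ETO lists in the HSF1 knockdown.

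Many of the same genes differed from control in the same direction in both knockdowns. SERPINE2, CPA4, IL6, ANTXR2, RPL26L1, IL7R, ANXA3 and MCTP1 (1.69 and 2.20) had the largest changes among genes higher in both, and TMT1A, GXYLT2, VIT, C1RL, CCNG2, CACNB2, DSEL and C1QTNF6 among genes lower in both. In total 251 probe sets were higher and 888 lower in both, where independent lists of these sizes would share 24.2 and 112. Simulated unchanged groups with common simulated controls shared 0. They held no effects that could be called, so this says nothing of how much sharing the common controls give. The shared calls were 47.2% of the calls of the HSF1 knockdown and 53.4% of those of the CBFA2T2 knockdown. Across genes, which are not independent replicates, the fold changes correlated with r = 0.71, against a mean of 0.50 and a highest value of 0.52 in 100 simulations, and had a covariance of 0.162 against a simulated 0.028, a difference of 0.134. The 3 control arrays were too few to split with 2 on each side, so part of the excess over independent lists may come from sharing them. The 6 knockdown arrays were also those with higher hybridisation controls. Left-out arrays that moved the shared count of 1139 by over 1.5 times were control replicates 1, 2 and 3, with 668, 631 and 732 genes, and HSF1 knockdown replicate 2, with 759.

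In opposite directions 3 genes were called, 5 without HSF1 knockdown replicate 1. There were 7 with array weights, 10 without moderation, 14 without the dimmest 30% and 20 with a trended robust prior. DDAH1, an enzyme that degrades methylarginines, was at -1.22 in the HSF1 knockdown and 1.57 in the CBFA2T2 knockdown, GRAMD1B, a sterol transporter, at -0.93 and 0.89, and DCBLD2 at -0.72 and 0.74. The calls of DCBLD2 each ended with 4 of 9 arrays left out in turn (highest adjusted p = 0.088 and 0.084), and its call in the HSF1 knockdown also after quantile normalization.

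**Figure D3:**
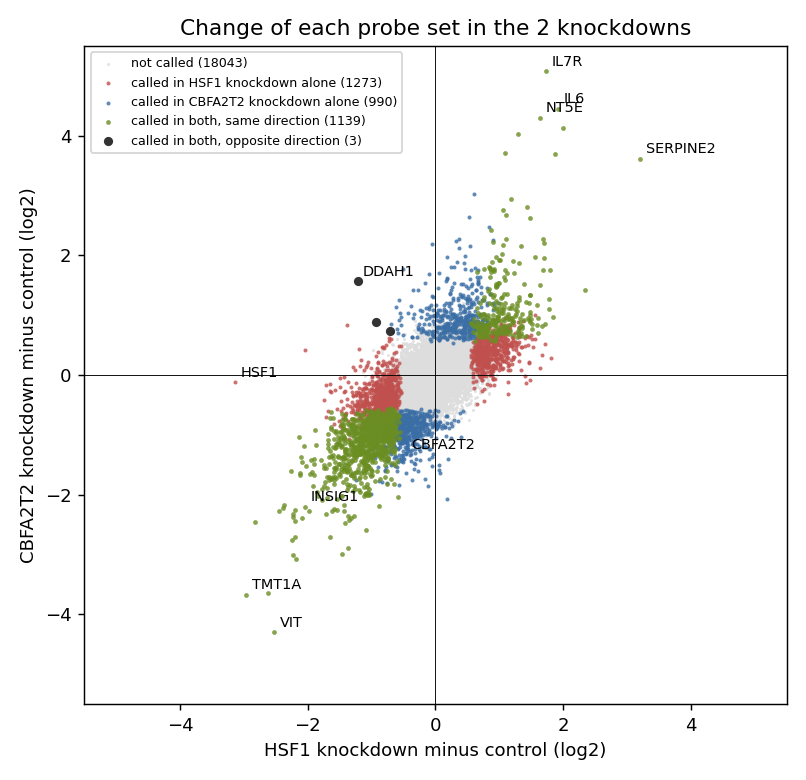
Log2 difference from control in HSF1 knockdown (horizontal) and CBFA2T2 knockdown (vertical) for each of 21448 probe sets, coloured by call. The 1139 probe sets called in the same direction in both lie along the diagonal, with 3 called in opposite directions.

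Set directly against each other, the knockdowns differed at 168 probe sets higher and 253 lower in HSF1 knockdown cells, 1.96% of those tested, and the arrays did not overlap at 20.3%, where chance gives 10%. HSF1 knockdown cells had less IL7R (-3.35, SE 0.22), HSF1 (-3.02), DDAH1 (-2.78), CDCP1 (-2.74), NT5E (-2.66) and DUSP5 (-2.62), and more of the cytochrome CYB5A (2.25, SE 0.31), VIT (1.77), TSPAN17 (1.74), TRIM29 (1.71), SLC25A10 (1.64) and the translation factor EIF4H (1.61). CYB5A and VIT lost their calls without moderation. CBFA2T2 itself was 0.85 higher in HSF1 knockdown cells and not called (adjusted p = 0.075). These counts depended on the fit: 51 higher and 123 lower with only the 6 arrays compared, 333 and 448 without the dimmest 30%, and 557 and 673 with a trended robust prior. With 1 array left out, they ran from 53 and 121 without HSF1 knockdown replicate 3 to 117 and 194 without control replicate 2. Leaving out HSF1 knockdown replicate 1 gave 61 and 178, and its replicate 2 gave 70 and 137. Leaving out CBFA2T2 knockdown replicates 1, 2 and 3 gave 93 and 168, 65 and 128, and 82 and 147. Leaving out control replicates 1 and 3 gave 95 and 188, and 109 and 190.

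The NF-kB list was lower in HSF1 knockdown than in CBFA2T2 knockdown cells, 6 of 21 (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.2e-05, and adjusted p = 0.046 with an estimated correlation), with IL6 at -2.53, TNFAIP3 at -2.24 and CXCL8 at -1.69. Heat shock chaperones were lower, 3 of 26 (8 adjusted over the list alone; camera adjusted p = 1.8e-05, and adjusted p = 0.079 with an estimated correlation), with HSPH1 at -1.36, DNAJB1 at -1.04 and HSP90AA1 at -0.75. DNAJB1 and HSP90AA1 were not called with only the 6 arrays compared, and lost their calls with 5 and 9 of 9 arrays left out in turn (highest adjusted p = 0.11 and 0.12, both without HSF1 knockdown replicate 2). Against control, the chaperone list had a median of -0.11 in the HSF1 knockdown and was not called. In the CBFA2T2 knockdown its median was 0.19, and it was called higher at the preset correlation. At the preset correlation 8 more lists were lower. ATF4 targets had 2 of 23 lower (6 adjusted over the list alone; adjusted p = 0.079 with an estimated correlation), led by CHAC1 at -1.75. The dedifferentiated state list had 3 of 20 lower and 1 higher (7 and 2 adjusted over the list alone; adjusted p = 0.078 with an estimated correlation), with NT5E at -2.66 and THBS1 at -1.30. ERK targets had 4 of 20 lower (4 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation), with DUSP5 at -2.62 and PHLDA1 at -1.55. Endoplasmic reticulum chaperones and unfolded protein response genes had 1 of 19 lower, EDEM1 at -1.44. Adjusted over the list alone, 4 were lower and 1 higher, and camera with an estimated correlation gave adjusted p = 0.11. Interferon-stimulated genes had 3 of 26 lower, IFIT1 at -1.11, IFI44 at -1.02 and RIGI at -0.99 (7 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation). The call of IFIT1 ended with each of 9 arrays left out in turn (highest adjusted p = 0.15, without HSF1 knockdown replicate 3), that of RIGI with 5 and that of IFI44 with 3 (0.095 and 0.073, both without HSF1 knockdown replicate 2). Apoptosis regulators had 1 of 15 lower, MCL1 at -1.15 (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), and lost the call without CBFA2T2 knockdown replicate 2 (adjusted p = 0.093). Immediate early genes had 4 of 16 lower and 1 higher (7 and 3 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation), with DUSP1 at -1.70. Their call ended without HSF1 knockdown replicate 2 (0.053). Matrix genes had 2 of 25 lower (4 adjusted over the list alone; adjusted p = 0.20 with an estimated correlation), with ITGA5 at -2.29. Their call ended without HSF1 knockdown replicates 2 or 3 or CBFA2T2 knockdown replicates 1 or 2 (adjusted p of 0.069, 0.11, 0.055 and 0.15). Another 5 lists were higher at the preset correlation. Cholesterol synthesis had 0 of 20 called (0 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Oxidative phosphorylation had 0 of 21 (5 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation). G2 and mitosis had 2 of 27 higher, MKI67 at 1.14 and KIF20A at 0.86 (4 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). KIF20A lost its call with each of 9 arrays left out in turn (highest adjusted p = 0.13, without HSF1 knockdown replicate 2). The proteasome had 1 of 27 higher, PSMC3 at 0.85 (3 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation). TRiC had 1 of 7 higher, CCT7 at 0.86 (1 adjusted over the list alone; adjusted p = 0.20 with an estimated correlation). Its call ended without HSF1 knockdown replicate 2 or CBFA2T2 knockdown replicate 3 (adjusted p = 0.074 and 0.080). PSMC3 and CCT7 each lost their calls with 6 of 9 arrays left out in turn (highest adjusted p = 0.082 and 0.090, both without HSF1 knockdown replicate 3). Autophagy was not called, but was without HSF1 knockdown replicate 1 (0.030) or CBFA2T2 knockdown replicate 3 (0.029). Fry also called S phase genes (0.010), glycolysis (0.049) and ribosome biogenesis (0.041), which camera did not. Median, mean and test differed in sign here for the ETO, melanocytic, leukocyte, p53 and keratinocyte lists.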

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

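Of the tests in this part, only the counts over other splits of the arrays were chosen before their results were seen. All others were chosen after, as was a margin of 2 binomial standard errors, added once the first outcomes of the quantile normalization test and of the chaperone interval test had been read, which left both undecided. A margin of 2 jackknife standard errors was likewise added to the test with the hybridisation controls after its value had been read, and that explanation, at first taken as argued against, became undecided.

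The hybridisation and labelling controls, which no comparison used, were higher in knockdown arrays than in control arrays. Array medians of negative control introns, not tested, ran from 4.65 to 4.79 in control arrays and 4.59 to 4.83 in knockdown arrays. Those of positive control exons, also not tested, ran from 11.41 to 11.53 in control arrays and from 11.48 to 11.61 in CBFA2T2 knockdown arrays. In HSF1 knockdown arrays they ran from 11.73 to 11.75, above every array of the other groups. The 4 hybridisation controls were 0.81 higher on the log2 scale (higher in 6 of 6 knockdown arrays than in any control array; exact two-sided permutation p = 0.012, the smallest that 84 splits can give, adjusted p = 0.024) and the 4 labelling controls 0.36 higher (also 6 of 6; exact two-sided permutation p = 0.024, adjusted p = 0.024).

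The shared response of both knockdowns was weighed first. The simulated correlation from shared control arrays reached 0.517 at most, below the observed 0.706. This argues against noise that is independent between probe sets in those arrays as the whole cause. The simulation held no noise common to many probe sets, so such noise in the control arrays stays open. With the hybridisation control level as a covariate, the median change of the 1139 shared genes was 0.938 of its value in the HSF1 knockdown (jackknife SE 0.113) and 0.943 in the CBFA2T2 knockdown (0.138), but the groups explained 91.4% of the spread of that level, the median SE of these genes went from 0.19 to 0.52 and 0.59, and 0 probe sets were called, so this explanation stays open. Quantile normalization narrowed the range of median changes over 10 classes of brightness from 0.30 to 0.02 in the HSF1 knockdown and from 0.24 to 0.03 in that of CBFA2T2 and left 969 probe sets called the same way in both, with r at 0.680, which argues against a brightness-dependent normalization as the whole cause, but 780 of the 1139, 68.5% (binomial SE 1.38), is too near the bound set to settle whether it contributed. A batch that sets the control arrays apart cannot be told apart from the knockdowns: the gap on the first principal component was 55.7, and no label gives a batch. Such a batch, an effect common to the shRNAs against both targets, and a biological effect common to both genes, which was not tested, stay open.

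The lower cholesterol list was weighed against the trend of fold change with brightness. Its medians in both knockdowns, -1.30 in that of CBFA2T2, lay at percentile 0 of 10000 random lists matched on brightness, whose middle 95% ran from -0.48 to 0.11 and from -0.38 to 0.12. The brightness trend alone is thus argued against in each. Whether the change belongs to the knockdowns or to a batch stays open, as for the shared response.

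The heat shock chaperone list was not called in HSF1 knockdown cells, with 19.2% of its members lower, against 7.67% of all probe sets. Of 1926 others in the middle brightness range of the chaperones, 21.5% were lower. That range is narrower than that of all 26 members. Of those 1926 probe sets 29.8% were called in either direction, against 11.3% of all, but the share called also follows precision, so compression of bright probe sets stays open. For 20 of 26 chaperones the 95% interval excluded a halving of their level, which is too near the bound set for this test to say that precision was enough for the list as a whole. No biological explanation was tested.

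Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. The real split was the 1 with the most calls in each comparison, with 2415, 2132 and 421 probe sets for HSF1 knockdown against control, CBFA2T2 knockdown against control and the knockdowns against each other, and the highest of the other splits gave 0 in each. Every other split mixes arrays of both groups, so any difference between the groups, also from a batch, widens its spread and lowers its calls. The contrast with 0 is thus no support for the knockdowns as the cause.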

How the results depend on the processing

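Scaling to the hybridisation controls, the one alternative chosen after seeing the data, gave 76 higher and 13718 lower probe sets in the HSF1 knockdown, 101 and 16300 in the CBFA2T2 knockdown and 161 and 105 between the knockdowns, since it lowers every value of the knockdown arrays. For the other moved counts the cause was not tested, beyond fewer arrays or probe sets. Quantile normalization gave 1078 lower in the HSF1 knockdown, and a log2 difference of HSF1 in the CBFA2T2 knockdown of 0.046 in place of -0.11. Between the knockdowns there were 333 higher and 448 lower without the dimmest 30%, 557 and 673 with a trended robust prior, 51 and 123 with only the 6 arrays compared. Genes called in opposite directions numbered 14 without the dimmest 30%, 20 with the trended prior, 10 without moderation and 7 with array weights. With an estimated correlation 1 list was called in the HSF1 knockdown, 5 in the CBFA2T2 knockdown and 1 between the knockdowns, and fry called 18 in the HSF1 knockdown. A pseudocount was not run because the values are logarithms.

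With the replicate block 86 probe sets were higher and 163 lower between the knockdowns, 632 and 1364 in the HSF1 knockdown and 535 and 1253 in the CBFA2T2 knockdown. Of the named pairs 29 lost their call and 3 gained one, and the numbers of lists called did not change. Deviations of same-numbered arrays correlated across probe sets at -0.07 to 0.03, against -0.12 to 0.13 for other pairs. Of the arrays, 0 correlated best with their own number. This gave no sign of a shared culture or day but cannot exclude one, and the labels do not say.

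With 1 array left out, probe sets in the HSF1 knockdown ran from 407 to 784 higher and 958 to 1658 lower, in the CBFA2T2 knockdown from 360 to 646 and 918 to 1441, and between the knockdowns from 53 to 117 and 121 to 194. Genes shared in direction ran from 631 to 1022 and opposite ones from 2 to 5. HSF1 stayed at -3.21 to -3.09 and CBFA2T2 at -1.56 to -1.17 in their own knockdowns. Of 280 called gene and comparison pairs named by the rule, 84 lost the call under an alternative, 78 of them with an array left out, and 0 changed sign. LYZ between the knockdowns, not called, ran from -0.062 without HSF1 knockdown replicate 3 to 0.24.

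Other reversals were of lists that were not called, given here as camera adjusted p. Quantile normalization turned heat shock chaperones in the HSF1 knockdown (0.644) and glycolysis (0.470) and oxidative phosphorylation (0.831) in the CBFA2T2 knockdown. Removing the dimmest 30% turned heat shock chaperones (0.990) and endothelial markers (0.705) in the HSF1 knockdown. It also turned glycolysis (0.841) and fibroblast markers (0.981) in the CBFA2T2 knockdown and keratinocyte markers (0.749) between the knockdowns. By fry the ETO (0.270) and autophagy (0.749) lists turned in the HSF1 knockdown.

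Some lists turned with at least 1 array left out, and their adjusted p over all such fits ran as follows. In the HSF1 knockdown it was 0.565 to 0.951 for autophagy, 0.464 to 0.982 for heat shock chaperones and 0.358 to 0.997 for immediate early genes. It was 0.714 to 0.985 for ETO and 0.619 to 0.980 for endothelial markers. In the CBFA2T2 knockdown it was 0.539 to 0.998 for glycolysis and 0.111 to 0.835 for oxidative phosphorylation. Between the knockdowns it was 0.502 to 0.942 for HSF paralogs, 0.134 to 0.881 for histones, 0.477 to 0.960 for leukocyte markers and 0.658 to 0.995 for fibroblast markers. It was 0.507 to 0.995 for keratinocyte markers, 0.541 to 0.982 for p53 targets and 0.381 to 0.982 for antigen presentation.

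Signal over background limits the dim probe sets: 36 of 60 named extremes had a dimmer group under the 95th percentile of negative controls. Most tested values lay under that percentile as well.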

Other observations

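Gene families were grouped by the letters before the first digit of their symbols and tested after the data were seen. A family can thus hold genes that share the letters but not the function, such as kinases named after a ribosomal protein. Camera was run over 126 families of at least 15 members, and 0 of the families below were called with an estimated correlation. In HSF1 knockdown cells cytosolic ribosomal proteins of the large subunit (RPL) had a median log2 difference of 0.64, with 11 of 34 higher and 0 lower (adjusted p = 1.1e-09, and adjusted p = 0.60 with an estimated correlation). Genes with the letters RPS, which name proteins of the small subunit but also other genes, had a median of 0.45. Of these, 6 of 34 were higher and 1 lower (adjusted p = 0.0013, and adjusted p = 0.62 with an estimated correlation). Mitochondrial ribosomal proteins had medians of 0.41 in the large subunit (MRPL), with 13 of 47 higher and 0 lower (2.0e-06), and 0.38 in the small subunit (MRPS), with 8 of 27 higher and 2 lower (5.0e-04). Genes with the letters EIF, which name translation factors but also other genes, had a median of 0.24, with 11 of 49 higher and 3 lower (0.0091). Keratin genes (KRT) had a median of 0.27, with 4 of 46 higher (9.4e-04). These 4 families had adjusted p = 0.47 with an estimated correlation.

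In CBFA2T2 knockdown cells keratin genes had a median of 0.34, with 5 of 46 higher (adjusted p = 0.0044, and adjusted p = 0.42 with an estimated correlation). Intraflagellar transport genes (IFT) had a median of -0.34, with 4 of 18 lower, and tetraspanins (TSPAN) -0.32, with 4 of 22 lower (both 0.039, and adjusted p = 0.42 with an estimated correlation). The RPL median was 0.21, with 2 of 34 higher, and the MRPL median 0.20, with 0 of 47 called (both 0.039, and adjusted p = 0.80 and 0.60 with an estimated correlation).

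In HSF1 knockdown minus CBFA2T2 knockdown cells the medians were 0.35 for RPL (adjusted p = 1.3e-05), 0.45 for RPS (0.0019), 0.19 for MRPS (0.0057) and 0.21 for MRPL (0.019). Of these, 1 gene was called, in MRPL, and their adjusted p was 0.84 for MRPS and 0.86 for the others with an estimated correlation. Dual-specificity phosphatases (DUSP) had a median of -0.26, with 4 of 23 lower (adjusted p = 0.0021, and adjusted p = 0.53 with an estimated correlation). All medians given here kept their sign after quantile normalization and after median centring.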
